A study of Mus musculus with 2 samples.

How the data were processed

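Adductor muscle of WT and Apoa1bp-/- mice was collected on day 7 after femoral artery ligation. Per the labels' protocols, the muscle was digested with collagenase D, strained and sequenced as droplet single-cell libraries with a cell barcode and a unique molecular identifier (UMI). The groups were taken from the genotype label, 1 library each. Surgery was done on 4 mice per genotype, and whether their cells were pooled is not given. The deposited matrices hold raw UMI counts per gene and barcode, not normalized. They were made with Cell Ranger, version 2.1.1 per the submitters' processing notes and version 5.0.0 per the file headers, and this difference could not be settled. The genome build and annotation are not given in the sources used here, so no coordinates are reported. GENCODE annotation was used only for Y-linked names, exon lengths and overlaps between genes.

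The files held 32574 genes. Barcodes with under 200 genes (49 WT, 31 knockout) or over 10% mitochondrial UMIs (149 and 197) were removed. Scrublet, as in scanpy, called 10.9% of WT and 5.86% of knockout barcodes doublets, against expected shares of 11.2% and 7.51% (0.8% per 1000 barcodes), and 1510 and 544 were removed. The kept cells held 66782967 WT and 72585356 knockout UMIs, with medians of 1672 and 2139 genes per cell. Both libraries were clustered together without integration, from 2000 variable genes, 30 principal components and 15 neighbours, with Leiden clustering at resolution 1.0 run until no change, which gave 29 clusters. The endothelial class was sub-clustered with 1500 variable genes, 20 components and resolution 0.8. Python 3.11.15, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16 were used.

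Clusters were called "X-like" from markers fixed before the data were examined. A marker counted where at least 25% of the cluster's cells had it, at least 2-fold above the median cluster with 5 CPM added. A name needed 3 such markers, no larger number of another class's markers among the 10 leading genes by fold, and no unrelated list with at least 0.67 of its marker share. This last limit, the rule on the leading marker, the number of Leiden iterations, and dropping a second round of clustering for unnamed clusters were set after the clusters and their counts per library had been seen. Earlier, clustering stopped after 2 iterations and any second lineage left a cluster unnamed. Both earlier rules were kept as alternatives, and the shares of the 5 unnamed clusters are given. Leaving haemoglobin genes out of the sub-clustering was tried because it would let a capillary sub-cluster be named, and was kept only as an alternative.

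The partition depends on rounding in the linear algebra library. An earlier run with another processor kernel gave a different partition, in which the sub-cluster led by Pgf was unnamed that is named tip/angiogenic here. The kernel was fixed so that the values can be computed again, not by its result, and 2 other kernels and 3 other seeds were added as alternatives. In all, 13 clusterings of all cells gave 23 to 54 clusters, 854 to 1111 endothelial-like cells and 16.4 to 33.0% of cells unnamed. Subtype shares were computed in 16 configurations.

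UMI counts were summed per library and class and given as CPM of the class total with exact Poisson intervals. Ratios of CPM have exact conditional intervals, and shares of cells exact Clopper-Pearson intervals, all at 95% and for counting error only. Log2 ratios used a prior count of 0.5. No test, p-value or count of changed genes was computed, since cells are not replicates. The 31 gene lists were fixed beforehand. A list's median log2 ratio over members of at least 5 CPM in either library was placed among 10000 random lists matched on mean expression in 20 bins. A list needed 5 measured members, and members at least 25% higher, or at least 20% lower, were counted, limits that were not among the choices fixed beforehand. Classes of at least 200 cells in each library were used. Shares of cells with a UMI were compared after thinning each cell to 1000 UMIs.

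Named genes followed a rule fixed beforehand: at least 20 CPM in either library, ranked by the bound of the ratio's interval nearest 1, with the 12 highest and 12 lowest named in the endothelial class and 5 each way in other classes. Ribosomal protein, mitochondrially encoded, haemoglobin, sex-linked and clone-named genes were left out of the ranking (4 of the highest and 3 of the lowest endothelial genes). Genes at 10 times the level in another named class of the same library, which free RNA could carry in, were left out too (2 and 12). That rule did not cover unnamed clusters. Of each described list, the 2 to 4 members with the largest log2 ratio and the member with the most UMIs could be named. Genes of the unnamed clusters 7 and 11, and of the pericyte- and muscle fibre-like cells, are not described one by one, and 1 gene that the rule names in another class is not reported here.

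The steps were tested on simulated endothelial sums of 6280 genes, with 99 genes changed 2-fold and 99 changed 4-fold. All were recovered (100%), intervals covered 95.0% of the true ratios, a list with a true log2 ratio of 1.0 gave 0.98, and 1 of 30 unchanged lists lay outside the central 95%. Both simulated libraries were Poisson draws from an averaged profile, so this checks the computation only. It held no variation between libraries, and no joint change in the unchanged lists. It thus does not tell how often real lists would lie outside without a genotype effect. Alternatives fixed beforehand were a mitochondrial limit of 20%, at least 500 genes per cell, doublets kept, Leiden resolution 0.5 for all cells or for endothelial cells, each library clustered on its own, edgeR TMM scaling, CPM without mitochondrial, ribosomal protein and haemoglobin genes, the mean of each cell's CPM, thinning, endothelial cells without a Ptprc or Pdgfra UMI, and list minimums of 20 and 1 CPM. Sub-clustering without the 3753 genes differing at least 1.5-fold, and the set of endothelial cells outside sub-clusters with 3 markers of another cell type, were added after the data were seen.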

Results

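Single-cell RNA sequencing was performed on adductor muscle of WT and Apoa1bp-/- mice on day 7 after femoral artery ligation, a surgery that cuts off the main arterial supply of the hind limb. Apoa1bp, now named Naxe (ENSMUSG00000028070), encodes AIBP, a protein that binds apolipoprotein A-I and repairs damaged NAD(P)H as the NAD(P)HX epimerase. Surgery was done on 4 mice per genotype, with control littermates as WT, and 1 library per genotype was analysed. Whether the 4 mice were pooled in it is not given in the sources used here. The WT library held 14035 barcodes and 80954991 UMIs, and the knockout library 9392 barcodes and 80444279 UMIs. After filtering, 12327 WT cells with a median of 4169 UMIs and 8620 knockout cells with a median of 6602 UMIs were kept. With 1 library per genotype no difference has a replicate check, so no test between genotypes was made. All intervals are exact 95% intervals that cover counting error only, and every ratio is knockout over WT.

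The targeted gene was examined first. Naxe had 3331 UMIs in the kept WT cells, or 49.9 CPM (48.2 to 51.6), and 0 UMIs in the kept knockout cells, with an upper limit of 0.0508 CPM. The upper bound of the ratio was 0.00102. No UMI of Naxe was found in any of the 9392 knockout barcodes either. In endothelial-like cells it had 102 UMIs in WT (43.2 CPM, 35.2 to 52.4) and 0 in the knockout, with an upper bound of 0.017 for the ratio. Naxd, which encodes the dehydratase that acts in the same NAD(P)HX repair pathway, was at 51.2 CPM in the WT and 57.6 CPM in the knockout library (ratio 1.13, 1.08 to 1.18).

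The first comparison asked which cell types made up the ischemic muscle in each genotype. Endothelial-like cells made up 3.69% of WT cells (455 cells, 3.37 to 4.04%) and 5.12% of knockout cells (441 cells, 4.66 to 5.60%), a ratio of 1.39 (1.21 to 1.58). This class leaves out the unnamed cluster 21, described below, which was led by endothelial genes. Its share ratio was 0.837, so counting it would lower the endothelial ratio. Neutrophil-like cells were at 0.576% in the WT and 2.49% in the knockout library (ratio 4.33, 3.30 to 5.75), and monocyte-like cells at 0.495% and 2.07% (ratio 4.17, 3.10 to 5.68). Satellite cell/myoblast-like cells, the progenitors of regenerating fibres, were at 9.94% and 13.4% (ratio 1.35, 1.24 to 1.46). Fibroblast-like cells were lower in the knockout library, at 17.2% against 30.2% in WT (ratio 0.569, 0.536 to 0.605). The lower shares of fibroblast-like cells and of the unnamed cluster 4 (9.41% and 1.77%) raise the shares of all other classes. No ratio was computed without them, so a higher share, as for endothelial-like cells, does not show that a class grew in number.

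Among smaller classes, the knockout share was higher for pericyte-like cells (1.65% WT, 2.83% knockout, ratio 1.72), muscle fibre-like cells (1.73% and 3.27%, ratio 1.89), NK cell-like cells (0.884% and 1.71%, ratio 1.93) and Schwann cell-like cells (0.665% and 1.76%, ratio 2.65). It was also higher for B cell-like cells (0.487% and 0.835%, ratio 1.72) and tenocyte-like cells (0.154% and 0.696%, ratio 4.52). T cell-like cells were at 1.74% and 1.97%, and the interval of their ratio (0.919 to 1.39) held 1. These are shares of a whole, and the gap in depth between the libraries lies beside all of them: endothelial-like cells had a median of 2708 UMIs in the WT and 8158 in the knockout library.

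Macrophage-like cells made up 26.9% of WT and 32.5% of knockout cells, but 5 clusters with mixed or conflicting markers stayed unnamed and held 20.9% of WT and 14.1% of knockout cells. Cluster 4, led by Cd163, Fcna and Lyve1 and nearest to macrophages, held 9.41% of WT and 1.77% of knockout cells. It had 9 of 10 macrophage markers, and stayed unnamed because Lyve1, which is also a lymphatic marker, was among its leading genes. The ratio of its shares was 0.189 (0.158 to 0.223). Some of its leading genes were also lower within other cells of the knockout library. Fewer such cells and lower expression of these genes cannot be told apart here. Cluster 7, led by the dendritic cell genes Cd209a and Ccr7, held 5.61% and 4.39%, cluster 11 (Cfd, Mmp9, Birc5) 3.24% and 3.81%, cluster 17 (Myog, Mymk) 1.22% and 2.96%, and cluster 21 (Selp, Vwf) 1.43% and 1.19%. With clusters 4 and 11 added to the nearest class, macrophages came to 39.5% and 38.1%, so no direction was read for macrophages. Cluster 21 was nearest to fibroblasts (8 of 10 markers), which came to 31.6% and 18.4% with it. It was left unnamed for endothelial and macrophage markers, and its leading genes Selp, Vwf and Lrg1 are venous endothelial markers. Its 176 WT and 103 knockout cells (ratio 0.837, 0.650 to 1.07) were counted neither as endothelial-like nor as fibroblast-like.

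The libraries also drew on different clusters within a class. Among macrophage-like cells, cluster 0 held 13.6% of WT and 11.2% of knockout cells, cluster 2, led by Cx3cr1 and class II antigen presentation genes, 3.72% and 10.5%, and cluster 18, led by the interferon-induced genes Cxcl10, Rsad2 and Ifit2, 1.10% and 3.09%. Among fibroblast-like cells, cluster 3 (Pi16) held 9.31% and 2.05%, cluster 8 (Cxcl14, Smoc2) 7.0% and 2.22%, and cluster 1 (Tnc, Cthrc1, Postn) 7.89% and 8.58%. Cluster 13, the satellite cell/myoblast cluster led by cell cycle genes such as Cenpf and Top2a, held 1.27% of WT and 4.03% of knockout cells.

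**Figure D1:**
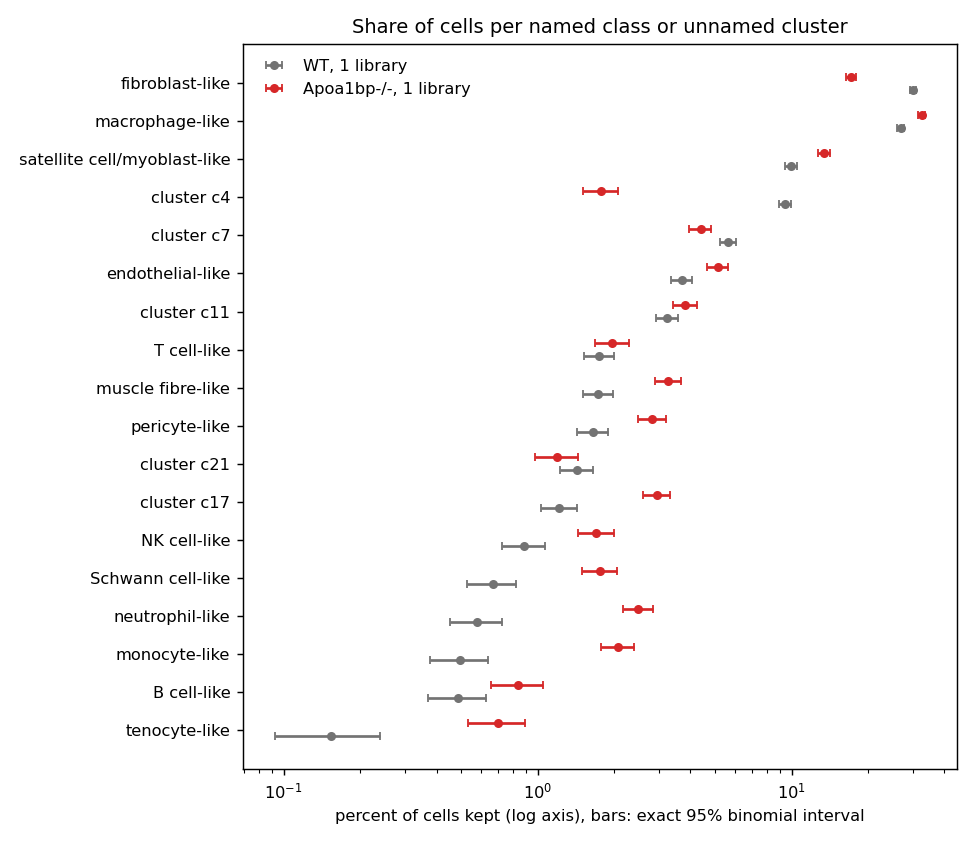
Share of kept cells (percent, log axis) in each named class or unnamed cluster of the WT (grey) and the Apoa1bp-/- library (red), with bars for the exact 95% binomial interval. Fibroblast-like cells and cluster 4 lie lower in the knockout library, and endothelial-, neutrophil- and monocyte-like cells lie higher. These are shares of a whole, so the lower ones raise the others.

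The second comparison, named in the series title, was of endothelial gene expression. Interferon-induced genes were higher in the knockout library: the list median was 0.96 on the log2 scale, at percentile 100 of 10000 expression-matched random lists, whose central 95% ran from -0.36 to 0.17. Of its 15 measured members, 13 were at least 25% higher and 0 at least 20% lower (the inverse ratio), the limits used for all lists. Isg15, a ubiquitin-like protein induced by interferon, was at 188 CPM in WT and 634 CPM in the knockout (ratio 3.38, 3.06 to 3.74), and Irf7, a transcription factor of the interferon response, at 71.1 and 161 CPM (ratio 2.26, 1.91 to 2.69). The GTPase Igtp (ratio 2.41) and Ifit2 (2.39) were also among the members with the largest ratios, and Ifitm3, the most abundant member, had a ratio of 1.35.

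With each cell thinned to 1000 UMIs, 15.1% of WT and 38.4% of knockout endothelial-like cells had an Isg15 UMI, and 78 WT and 32 knockout cells were too shallow to enter. Without thinning the shares were 34.7% and 76.6%. In satellite cell/myoblast-like cells, thinned in the same way from medians of 3942 and 7575 UMIs, they were 2.28% and 5.08%.

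Cell cycle genes were also higher, with a list median of 0.41 at percentile 100, and 13 of 20 measured members higher against 0 lower. With all 11 endothelial sub-clusters weighted by their pooled share, the median was -0.01 at percentile 76.0, inside the central 95%. Ube2c (ratio 1.93) and Ccna2 (1.86), which act in mitosis and in S phase, and Stmn1 (1.83), a regulator of microtubules, were examples. Birc5 had a ratio of 1.92, but its log2 ratio was -0.23 after thinning. After thinning, 1.59% of WT and 4.89% of knockout endothelial-like cells had an Mki67 UMI (7.25% and 18.1% unthinned), with overlapping intervals (0.586 to 3.43% and 3.01 to 7.45%), against 0% and 1.06% in neutrophil-like cells, whose median depths were 1239 and 1584 UMIs. Of the other 2 cell cycle genes thinned in this way, 3.45% and 5.87% of endothelial-like cells had a Top2a UMI and 5.31% and 4.65% a Birc5 UMI, also with overlapping intervals. In neutrophil-like cells these were 0% and 1.59% for Top2a, and 0% and 2.65% for Birc5. Only 54 WT and 189 knockout neutrophil-like cells were deep enough to enter.

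Angiogenic tip cell genes were lower in the knockout library, with a median of -0.63 at percentile 0.00, and 9 of 14 measured members lower against 1 higher. The chemokine receptor Cxcr4 was at 107 CPM in WT and 37.9 CPM in the knockout (ratio 0.354, 0.292 to 0.428). The growth factor Pgf (ratio 0.489), Esm1 (0.514) and Apln (0.529) were lower as well, and Kdr, the main VEGF receptor of endothelium, was at 650 and 443 CPM (ratio 0.681, 0.638 to 0.727). With the 7 sub-clusters of at least 20 cells per library weighted equally, which leaves out 4 smaller ones, the median was -0.28 at percentile 4.03, inside the central 95% of its random lists.

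Notch pathway genes were lower too (median -0.49, percentile 0.41), with 9 of 12 measured members lower and 0 higher. The ligands Jag1 (ratio 0.581), Dll4 (0.672) and Jag2 (0.686) and the receptor Notch1 (0.736) were lower. The target gene Heyl had a ratio of 0.615, but its log2 ratio was 0.11 in the endothelial-like cells outside sub-clusters with 3 markers of another cell type. The Notch percentile was 6.21 with doublets kept, 2.67 in that smaller set of cells and 8.70 in the 6 sub-clusters with a subtype name. Of the arterial endothelial genes (median -0.57, percentile 0.09), 8 of 11 were lower and 1 higher. They included Efnb2 (ratio 0.579), the ephrin ligand of arteries, and the chemokine Cxcl12 (0.664), while Gja5 (0.599) and Sema3g (0.661) turned to log2 ratios of 0.03 as a mean over cells and 0.24 after thinning. As a mean over cells, the arterial list lay at percentile 18.4, and with doublets kept at 5.88. Caveolae genes, which form the membrane pits of endothelium, had a median of -0.46 (percentile 0.52; 5 of 8 lower, 1 higher), with Cav1 at a ratio of 0.701 and Cavin1 at 0.648. Their percentile was 2.72 as a mean over cells and 3.31 with doublets kept.

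Of the energy metabolism lists, 3 were higher in the knockout library. Fatty acid oxidation had a median of 0.22 (percentile 99.2; 4 of 13 higher, 0 lower), with the acyl-CoA dehydrogenase Acadl at a ratio of 1.5. The tricarboxylic acid cycle had a median of 0.25 (percentile 99.8; 6 of 14 higher, 1 lower), with Idh3g at 1.52 and Mdh2 at 1.44. Mitochondrially encoded genes had a median of 0.33 (percentile 99.3; 7 of 13 higher, 1 lower), with mt-Co2 at 2.40, mt-Atp6 at 1.98 and mt-Nd6 at 0.318. The tricarboxylic acid cycle list lay at percentile 97.1 and the mitochondrially encoded list at 56.1 as a mean over cells, and at 82.1 and 93.4 after thinning, all inside the central 95%. Nuclear oxidative phosphorylation genes (0.12, percentile 96.2) and glycolysis (0.15, percentile 96.0; 98.7 with pooled weights over all 11 sub-clusters) lay inside the central 95%, but above it in 6 and 3 of 21 settings (up to percentiles 98.65 and 98.9, both after thinning). Uqcrb, a subunit of complex III, was at 340 and 700 CPM (ratio 2.06). The tricarboxylic acid cycle list also lay above the central 95% in fibroblast-like (0.28, percentile 99.6) and macrophage-like cells (0.16, 98.8). Mitochondrially encoded genes did so in macrophage-like (0.26, 99.4) but not in fibroblast-like cells (0.28, 94.6), and had -0.80 in muscle fibre-like cells. Fatty acid oxidation lay inside in fibroblast-like (84.8) and macrophage-like cells (88.3). Over all kept cells, the median mitochondrial share of UMIs was 1.37% in WT and 1.86% in the knockout.

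The lipid lists closest to the known function of AIBP in cholesterol efflux lay inside their random ranges when all endothelial-like cells were summed. LXR targets and cholesterol efflux genes had a median of -0.30 (percentile 10.8), but lay below the central 95% with doublets kept (percentile 0.61) and with 7 sub-clusters weighted equally (1.71) or by their pooled share (1.18). Of their members, the transporter Abca1 had a ratio of 0.639 (0.574 to 0.711) and Abcg1 0.658 (0.554 to 0.783). Cholesterol synthesis and uptake genes had a median of -0.05 (percentile 82.7). Endothelial fatty acid handling genes had 0.13 (percentile 86.3), with 5 of 10 higher and 4 lower. Fabp4, the most abundant, was at 17690 and 25154 CPM, while Lpl was lower, at 283 and 158 CPM (ratio 0.556, 0.501 to 0.617).

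The remaining lists outside the central 95% were the unfolded protein and integrated stress response (median -0.43, percentile 1.44; 8 of 12 lower, 0 higher; percentile 43.0 after thinning) and 3 lists that mark other cell types. Resident and repair macrophage genes had a median of -1.47 (percentile 0; 8 of 10 lower, 1 higher) and activated fibroblast genes -0.81 (percentile 0; 6 of 9 lower, 2 higher), but the latter lay at percentile 82.3 with another kernel for the linear algebra. Myogenic differentiation genes had a median of 0.56 (percentile 99.98; 6 of 12 higher, 1 lower) that turned to -0.33 after thinning. Thus 13 of 31 lists lay outside, 6 higher and 7 lower, and 11 to 15 did so under the other settings. In each of 21 settings the interferon, cell cycle and fatty acid oxidation lists lay above and the tip cell and resident macrophage lists below, and these were the only 5 lists outside in each of them. The 21 settings leave out the sub-cluster weights: with 7 sub-clusters, fatty acid oxidation lay inside at percentile 96.0 with equal and 95.6 with pooled weights, and so did the cell cycle, tip cell, unfolded protein and activated fibroblast lists with both. The unfolded protein list lay at percentiles 14.6 and 16.7, and the activated fibroblast median turned to 0.16 (89.5) and 0.15 (87.5). The tricarboxylic acid cycle list lay inside with equal weights only (97.1).

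The other lists lay inside when all endothelial-like cells were summed, but not in every setting. Their medians were -0.42 for angiogenic and growth factor ligands, -0.39 for shear-responsive and nitric oxide genes, -0.30 for endothelial junctions, -0.28 for TGF-beta/BMP signalling, -0.23 for basement membrane, -0.22 for venous genes and -0.14 for extracellular matrix. They were -0.04 for adhesion molecules and NF-kB targets, -0.04 for inflammatory macrophage genes, -0.01 for dissociation and immediate early genes, 0.02 for hypoxia-induced genes, 0.04 for lipid-associated macrophage genes and 0.06 for antigen presentation. Of the 21 settings, shear-responsive genes lay outside in 5, lipid-associated macrophage genes in 3, TGF-beta/BMP signalling, the ligands, extracellular matrix and inflammatory macrophage genes in 2 each, and junctions and adhesion molecules in 1 each. Inflammatory macrophage genes and adhesion molecules were measured in 20 of them. The sub-clusters that entered and their weights changed the calls as well. With 7 sub-clusters weighted equally, the venous list lay at -1.40 (percentile 0.0), extracellular matrix at 0.26 (99.7) and TGF-beta/BMP signalling at -0.30 (1.53). With pooled weights over the same 7, the venous list lay at -1.05 (0.0), adhesion molecules at 0.30 (97.9) and the ligands at -0.42 (2.37). In the 6 sub-clusters with a subtype name, extracellular matrix (percentile 0.415), venous (0.465) and shear-responsive genes (1.80) lay below the central 95%, and nuclear oxidative phosphorylation (97.7), antigen presentation (98.4) and dissociation genes (99.8) above it. Scaling the endothelial sums with edgeR's TMM raised all log2 ratios by 0.16, and the ranks against random lists set aside such a common shift.

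**Figure D2:**
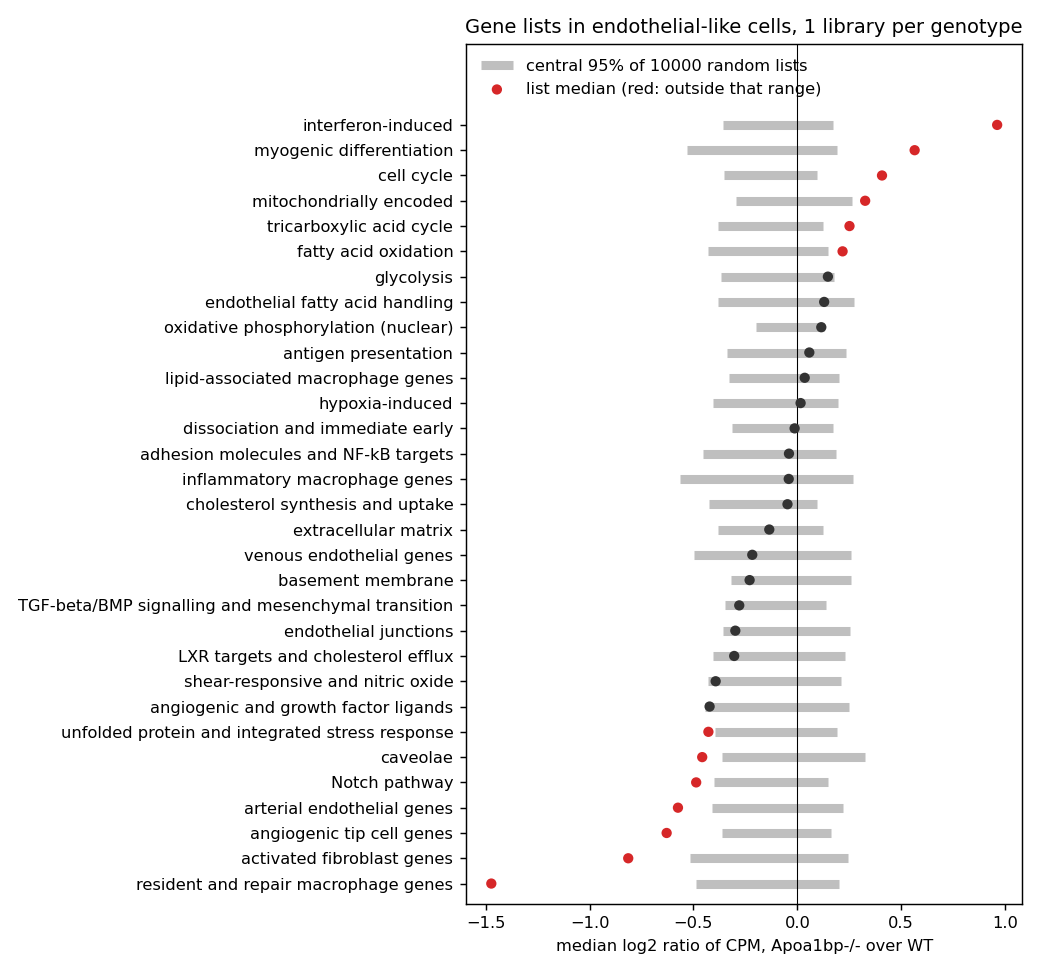
Median log2 ratio of CPM, Apoa1bp-/- over WT, of each of 31 gene lists in endothelial-like cells (points), with grey bars for the central 95% of 10000 expression-matched random lists. The interferon-induced list lies at 0.96, and the tip cell list at -0.63, both outside their bars (red).

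Ranked by the bound of the ratio's interval nearest 1, the 12 genes highest in the knockout endothelial-like cells were led by Myog and Isg15. They included the chromatin proteins Hmgn2 (135 and 328 CPM, ratio 2.43), H1f10 (3.49) and H1f5 (2.72), and Angptl4, an inhibitor of lipoprotein lipase (11.4 and 36.9 CPM, ratio 3.23, 2.15 to 5.03). Cyp26b1, which breaks down retinoic acid, had a ratio of 2.58. Apool (2.70), Itgb3bp (3.32), the replication factor Rfc4 (2.88), Irf7 and Uqcrb completed the group. Myog, a transcription factor of muscle differentiation, was at 2.96 and 44.4 CPM (ratio 15, 7.15 to 37.7), in 7 WT and 23 knockout endothelial-like cells. The myogenic cluster 17 held it at 5514 CPM in the WT and 6290 CPM in the knockout library.

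The lowest after Naxe was Retnla, a secreted protein of repair macrophages, at 128 CPM in WT and 1.37 CPM in the knockout (ratio 0.0107), and at 4092 and 828 CPM in the unnamed cluster 7. The transcription factors Maf (ratio 0.301) and Prdm1 (0.265), Ppp1r13l (0.188) and Igfbp5, an insulin-like growth factor binding protein (260 and 93.4 CPM, ratio 0.360), were lower. So were Fgl2 (0.330), the lymphatic marker Reln (0.317), the heat shock gene Hspa1b (0.341), Ntn4 (0.260), Stk40 (0.311) and Cxcr4. Reln had a UMI in only 3.08% of WT and 2.72% of knockout endothelial-like cells, and Fgl2 in 6.81% and 5.67%. Both are among the leading genes of the lymphatic sub-cluster, which held 16 and 12 cells. Of the 455 WT and 441 knockout endothelial-like cells, 115 and 107 lay in 3 sub-clusters with at least 3 markers of another cell type. A sub-cluster led by haemoglobin genes (140 and 27 cells) and one led by the muscle fibre genes Tnni2 and Ckm (14 and 24 cells) were not among these.

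Sub-clustering the endothelial-like cells gave 11 sub-clusters. The arterial sub-cluster held 8.13% of WT (37 cells, 5.79 to 11%) and 15.2% of knockout endothelial-like cells (67 cells, 12 to 18.9%), a ratio of 1.87 (1.23 to 2.87). The cycling sub-cluster held 3.96% (18 cells) and 7.71% (34 cells), a ratio of 1.95 (1.07 to 3.67). Since several arterial genes differed between the libraries, sub-clusters were also found without the 3753 genes that differed at least 1.5-fold, which gave 9.23% and 15.6% for arterial and 3.96% and 8.62% for cycling cells. Over 16 configurations of the clustering, the arterial ratio was 1.53 to 2.13 and the cycling ratio 1.81 to 2.33, above 1 in all 16. These configurations drew on largely the same cells, so they are not independent. The values are also shares of a whole. The sub-cluster led by haemoglobin genes held 140 WT and 27 knockout cells, which raises the knockout shares of the others. No ratio was computed without it. The arterial and cycling ratios would be lower then, and whether their intervals would still lie above 1 was not computed.

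The other subtypes depended more on the partition. The venous sub-cluster held 5.49% and 12.9% (ratio 2.35, 1.45 to 3.93), with 1.09 to 2.38 over the 16 configurations, and 1.09 without the differing genes. It held 25 and 57 cells. The unnamed cluster 21, led by the venous markers Selp, Vwf and Lrg1, was larger (176 and 103 cells) and lay outside the endothelial class. The direction for venous cells depends on whether cluster 21 is counted, so none was read. A tip/angiogenic sub-cluster, which rested on 3 of 8 markers, held 14.1% and 20.4% (ratio 1.45, 1.04 to 2.03). It was named in only 5 of the 16, with ratios of 1.24 to 1.45. Capillary cells were at 5.71% and 5.22%, with a ratio above 1 in 4 and below 1 in 10 of the 14 configurations that named them. Lymphatic cells were at 3.52% (16 cells) and 2.72% (12 cells), and the interval of the ratio (0.334 to 1.74) held 1. The largest sub-cluster, with 5 of 8 capillary markers but led by haemoglobin genes, stayed unnamed and held 30.8% of WT and 6.12% of knockout endothelial-like cells.

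The third comparison asked where else the same lists differed. Interferon-induced genes were higher in 7 of the 8 classes and clusters with at least 200 cells per library: the median was 0.75 in fibroblast-like, 0.82 in macrophage-like, 0.58 in pericyte-like and 0.49 in satellite cell/myoblast-like cells, 0.74 in cluster 7 and 0.94 in cluster 11. In muscle fibre-like cells it was -0.68, at percentile 52.4 of the random lists. Cell cycle genes lay above the central 95% in 7 of 8, with 1.16 in fibroblast-like, 1.00 in satellite cell/myoblast-like and 0.99 in pericyte-like cells. Resident and repair macrophage genes lay below it in 8 of 8. Some lists that were lower in endothelial-like cells were lower elsewhere too. The tip cell list lay below the central 95% in macrophage-like cells (-0.46, percentile 1.2), with only 5 members measured. In fibroblast-like cells it lay inside (0.22, percentile 95.9). Caveolae genes lay below the central 95% in fibroblast-like cells (-0.64, percentile 0.18), and inside it in macrophage-like cells (-0.30, percentile 9.71). Different clusters made up the fibroblast, macrophage and satellite cell classes in the 2 libraries, as given above for clusters 0, 1, 2, 3, 8, 13 and 18.

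**Figure D3:**
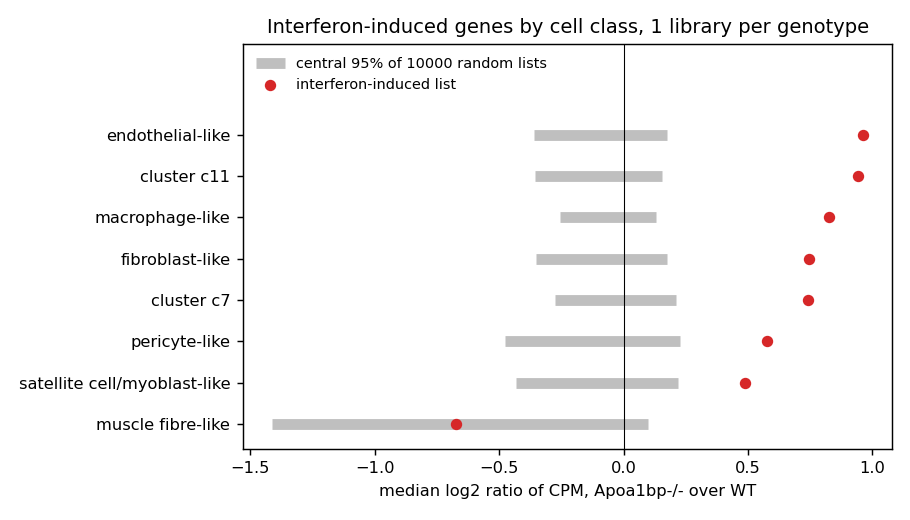
Median log2 ratio of CPM, Apoa1bp-/- over WT, of the interferon-induced list in each class or cluster with at least 200 cells per library (red points), with grey bars for the central 95% of 10000 random lists. The median lies above the bar in 7 of 8, and inside it for muscle fibre-like cells.

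Ranked by the same bound, the genes named as highest in macrophage-like cells were Rtp4 (43.2 and 136 CPM, ratio 3.14), Isg15 (3.01), Ifi213 (2.96), Ms4a4c (2.81) and Ifit3 (2.69). Of these, Isg15 and Ifit3 are on the interferon list. Plac8, Slfn4 and Ly6c2 ranked among them but were left out, since free RNA could carry them in. Beside Naxe, and with Col1a1 left out in the same way, the lowest were Retnla (269 and 25.3 CPM, ratio 0.0938), Ccdc152 (0.117), the serotonin receptor Htr2b (0.259) and the chemokine Ccl24 (0.265). Ccdc152 overlaps Selenop on the other strand in the GENCODE annotation, and the strand of counting is not given, so its value is uncertain. In fibroblast-like cells the chromatin factor Hmga2 (0.899 and 20.8 CPM, ratio 23.1), Crabp1 (9.98), Cxcl10 (5.12), Isg15 (4.66) and Dlk1 (4.44) were the highest. Dmkn (0.169), Cxcl13 (0.199), Myoc (294 and 64.4 CPM, ratio 0.219) and Ccdc152 (0.110) were the lowest beside Naxe, with Igkc, Igha, Jchain and Retnla left out in the same way. In satellite cell/myoblast-like cells Dlk1 (8.34 and 98.3 CPM, ratio 11.8) and Aard (5.39) were higher, and Retnla (0.0557), Hspa1a (0.266) and Hspa1b (0.282) lower. Dissociation and immediate early genes had a median of -0.59 there (percentile 0; 10 of 16 lower, 1 higher), and also lay below the central 95% in pericyte-like (-0.30, percentile 1.35) and muscle fibre-like cells (-0.99, percentile 1.76). The immunoglobulin genes Iglv1, Jchain and Igha ranked above Dlk1 in satellite cell/myoblast-like cells, but came from 0.0866% of the knockout cells.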

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

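Of the tests below, the weighting of sub-clusters for interferon and cell cycle genes, all weights by pooled share, all weights over 11 sub-clusters, and the 6 sub-clusters with a subtype name were chosen only after the results had been seen. Equal weights cover 7 sub-clusters with at least 20 cells in each library, and leave out 4, among them the cycling one.

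Interferon-induced genes were higher in the knockout library's endothelial-like cells. Deeper cells were argued against, since the list stayed at percentile 100 after thinning (median 0.81). Doublets gathered in sub-clusters of their own were argued against too. The list stayed at percentile 100 outside sub-clusters with 3 markers of another cell type (1.09) and in the 6 with a subtype name (1.13). Free RNA of other cell types stays open, since it can enter any cell and leaving out sub-clusters does not remove it. In the same 6, resident and repair macrophage genes still lay at percentile 0 (-1.37) and myogenic differentiation genes at 100 (1.13). Different sub-cluster shares were argued against, since the interferon list stayed at percentile 100 with equal weights (0.88) and with pooled weights over 7 (0.83) or all 11 sub-clusters (0.98). Within sub-clusters the interferon list lay above the central 95% in 9 of 11, among them one of only 12 WT and 2 knockout cells. It lay inside in the one led by haemoglobin genes (percentile 82.05), the largest in WT with 140 cells. It also lay inside in the one with pericyte markers (94.1), with 68 WT cells. It also stays open whether genotype or another difference between the libraries, such as handling or the pool of mice, lies behind the higher list. With 1 library per genotype these cannot be told apart.

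Cell cycle genes were higher there as well. Depth was argued against, since the list stayed at percentile 100 after thinning (0.53). Doublets gathered in sub-clusters of their own were argued against too. The list stayed at percentile 100 outside sub-clusters with 3 markers of another cell type (0.49), and at 99.91 in the 6 with a subtype name (0.25). Free RNA of other cell types stays open here too, since leaving out sub-clusters does not remove it. Weights over 7 sub-clusters, equal (percentile 19.0) or pooled (34.8), decided nothing, since they leave out the cycling sub-cluster and each library's own shares over the same 7 already gave percentile 94.1. Over all 11 sub-clusters the list was at percentile 100 with own shares (0.51) and 76.0 with pooled shares (-0.01), so different shares stay open as an explanation. The sub-clusters were themselves found from expression, and within them the list lay above the central 95% in 4 and below it in 1. The 4 include sub-clusters of only 12 WT and 2 knockout cells and of 16 and 12 cells.

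Angiogenic tip cell genes were lower there. Gene length was argued against, with percentile 0.0 among random lists matched on expression and exon length, and so was depth, with percentile 0.39 after thinning (median -0.57). Over 7 sub-clusters equal weights gave percentile 4.03 (-0.28) and pooled weights 2.96 (-0.31), both inside the central 95%, against 0.53 (-0.46) with each library's own shares. Over all 11, pooled shares gave 2.65 (-0.32) and own shares 0.0 (-0.68), so different shares stay open as an explanation, as does genotype with 1 library each. The medians stayed below 0 with each of these weights. The tip/angiogenic sub-cluster itself held a higher share in the knockout library (14.1% and 20.4%), so its own share would not lower the list. Within sub-clusters the list lay below the central 95% in 3 of 11: the tip/angiogenic one (2.39), one with pericyte markers (0.94) and one with macrophage markers (0.01).

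Some signals lay outside the comparisons. A haemoglobin UMI was found in 48.0% of WT and 10.3% of knockout cells kept. The Y-linked genes Ddx3y (58.4 CPM in WT, 52.2 CPM in the knockout) and Eif2s3y (33.8 and 44.9 CPM) were found in both libraries, while Xist had 1 UMI in each.

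In 3 cases a list lay outside the central 95% of its random lists both in endothelial-like cells and in another cell class, with medians of opposite sign, and the difference between the classes was not tested. Mitochondrially encoded genes had a median of -0.80 in muscle fibre-like cells and 0.33 in endothelial-like cells. Myogenic differentiation genes had -0.29 in satellite cell/myoblast-like cells and 0.56 in endothelial-like cells. Cell cycle genes had -0.23 in cluster 11 and 0.41 in endothelial-like cells.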

How the results depend on the processing

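Seeds, kernels, 2 Leiden iterations, the stricter lineage rule, the sub-clusterings without haemoglobin or differing genes and the set outside other-type sub-clusters were chosen after seeing the data. No paired analysis was possible because each genotype had 1 library and no test was made. Naxe stayed at 0 CPM in the knockout and 49.9 to 50.3 CPM in WT in all settings. The endothelial share ratio was 1.36 to 1.42, except 1.2 with doublets kept. Arterial, cycling, lymphatic and tip/angiogenic ratios moved less than counting error wherever named. The capillary ratio was 0.244 with at least 500 genes per cell, 0.308 with 2 iterations, 0.283 with seed 4, 0.283 with the Nehalem kernel, 0.308 at sub-resolution 0.5 and 1.72 without haemoglobin genes. The venous ratio was 1.3 at a mitochondrial limit of 20%, 1.34 with 500 genes, 1.27 at resolution 0.5, 1.35 with 2 iterations, 1.24 with seed 2, 1.17 with seed 3, 1.41 at sub-resolution 0.5 and 1.09 without differing genes. The macrophage share ratio turned to 0.876 with each library clustered on its own and 0.952 with the stricter lineage rule. Except for scaling, which lifts all ratios alike, the cause of the changes given here was not tested.

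Of the list medians, basement membrane turned to 0.054 as a mean over cells and 0.12 after thinning, and extracellular matrix to 0.087 with 2 iterations, 0.092 with the Sandybridge kernel and 0.029 with TMM. Activated fibroblast genes turned to 0.034 with 2 iterations and 0.036 with Sandybridge, and myogenic genes to -0.33 after thinning and -0.055 without Ptprc or Pdgfra cells. Of the genes' log2 ratios, Heyl turned to 0.11 outside other-type sub-clusters, and Gja5 to 0.025, Lrg1 to 0.083 and Srebf2 to 0.17 as a mean over cells. Thinning turned Sema3g to 0.24, Birc5 to -0.23, Cgnl1 to 0.027 and Actc1 to -1.05. TMM turned Apoe to 0.0305, Klf2 to 0.012 and Jund to 0.075, and keeping doublets turned Cd63 to -0.024. Col1a1 turned to 0.087 and 0.091, Tnc to 0.34 and 0.33, and Postn to 0.034 and 0.036 with 2 iterations and Sandybridge. Sub-clusters of 2 to 140 cells per library limit the subtype shares, since their counting intervals span up to several-fold.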

Other observations

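Differences in fibroblast-like cells are given here, and several were also found in other classes. All 20 measured cell cycle genes were at least 25% higher in the knockout library (median 1.16, percentile 100), as were all 20 in satellite cell/myoblast-like cells. Glycolysis genes were higher (median 0.52, percentile 100; 10 of 17 higher, 2 lower), and so were inflammatory genes such as chemokines (0.79, percentile 100; 7 of 10 higher, 0 lower) and adhesion molecules and NF-kB targets (0.44, percentile 99.9). Cholesterol synthesis and uptake genes were lower (-0.54, percentile 0.01; 13 of 21 lower, 0 higher), as were LXR targets and cholesterol efflux genes (-0.54, percentile 0.25; 6 of 10 lower, 1 higher) and basement membrane genes (-0.59, percentile 0.04; 10 of 12 lower, 0 higher). Clusters 3 and 8 held 2011 of the 3723 WT cells of this class, and cluster 1 was its largest in the knockout library, with 740 of 1482 cells.

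In macrophage-like cells inflammatory genes were higher (median 0.34, percentile 99.9; 6 of 11 higher, 0 lower), and resident and repair genes lower (-0.52, percentile 0; 7 of 13 lower, 1 higher). Extracellular matrix genes, which fibroblasts make, were lower in these cells (-1.53, percentile 0; 14 of 15 lower, 0 higher) and in satellite cell/myoblast-like cells (-0.90, percentile 0; 15 of 17 lower, 1 higher), in a library with a lower share of fibroblast-like cells. They were also lower within fibroblast-like cells themselves (-0.36, percentile 0.215, with 9 of 17 lower and 2 higher). In pericyte-like cells nuclear oxidative phosphorylation genes (0.31, percentile 99.9) and glycolysis genes (0.41, percentile 99.9) were higher.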
